A study of Mus musculus with 24 samples.

How the data were processed

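Gene expression was measured with Affymetrix arrays in the caecum of 24 mice in 4 groups of 6: control or inulin diet, with or without Trichuris muris. Each array was taken as 1 mouse, as the sample titles state. The deposited values are log2 probe set summaries, and the median over all genes was 7.136 to 7.505 on the 24 arrays. The array labelling followed the manufacturer's biotin protocol per the labels. The background correction, the normalization and the summarization method are not given in the sources used here. Values ran from 1.01 to 19.58, and those above 16 exceed log2 of a 16-bit scanner reading, so the scale had been transformed further in a way that is not stated. All differences are therefore given in log2 units of the deposited scale and not as folds. No detection calls were used.

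The hybridization spike-ins lay in their order of concentration on 24 of 24 arrays (bioB 8.88, bioC 10.49, bioD 11.78, cre 12.86), and so did the poly-A spike-ins (lys 5.44, phe 6.60, thr 7.84, dap 9.58). The table held 28846 probe sets, of which 6640 were controls. Of the other 22206 probe sets, 19572 carried exactly 1 gene symbol and 2634 carried none. Where a gene had several probe sets, which was so for 55 genes, the one with the highest mean over all arrays was used, which left 19505 genes. All 19572 symbols were found by gene ID in the RefSeq table and 0 needed updating. The 23 background control probe sets had means of 2.0 to 7.73, with a mean of 4.91 and a median of 5.58. No filter on dim genes was applied, and 6188 genes had a mean below the mean of the background probe sets. Genome positions are not given, because the files used here name no genome build.

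All 24 arrays were fitted in 1 model with 4 group means in limma 3.58.1 under R 4.3.3, with its moderated two-sided test in default settings. The 5 contrasts were infection on the control diet, infection on the inulin diet, diet without infection, diet under infection, and the interaction, which is the response to infection on inulin minus that on the control diet. P values were adjusted by the Benjamini-Hochberg method over the 19505 genes of each contrast, and the threshold was an adjusted p under 0.05 without a minimum size. Standard errors are those of the limma fit, and standard deviations (SD) are those between the 6 mice of a group. Principal components were computed on the values of all genes.

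The contrasts, the tests, 41 gene lists for immune responses, cell types, metabolism and stress, and the rule for naming genes were fixed before the data were examined. A list was tested when at least 5 members were measured, which left 40; the list for red blood cells had 2 measured members and was not tested. Lists were tested with camera of limma at its preset correlation between genes of 0.01, adjusted over the 40 lists of each contrast. Camera with an estimated correlation and fry, also of limma, were run beside it. Members past the threshold were counted over all genes and again adjusted over the list alone. Named genes were the 6 largest rises and 6 largest falls of each contrast, up to 4 members with the smallest adjusted p of each list that passed camera or had at least 3 members past the threshold, and a fixed panel of immune and epithelial genes. Predicted genes, small RNA genes and antigen receptor segments were left out of the largest rises and falls. Genes outside this rule are marked where they appear. Lists for small intestinal enterocytes, Paneth cell products and further muscle layer genes were added after the data were examined. The list of Paneth cell products was also tested on a part of its members. That part shares no symbol stem with the genes seen before the list was written or with list members that other lists also hold. A scan of 312 gene families that share a symbol stem was also added after the data were examined.

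The agreement of effects between contrasts was given as Pearson's r and Spearman's rho across genes, with a jackknife error over the arrays. The genes are not independent replicates, so no p value was attached. The number of genes shared between contrasts was set beside n1 times n2 divided by the number of genes. Calls were tested on simulated data with the same numbers of mice and genes: 200 of 19505 genes were given differences of 0.5, 1, 2 or 4 log2 units, 50 genes each. A difference of 1 was recovered for 60% to 66% of genes in the 4 group contrasts and for 30% in the interaction, and a difference of 2 for 96% to 100% and 90%. Differences of 0.5 were recovered for 2% to 20% of genes. Between 4.17% and 7.89% of the calls were false. The simulated genes varied independently of each other, with the same spread in every group, and the number changed was fixed at 200. These rates may therefore not hold for the real arrays. The 6 arrays per group limit the precision: the median standard error of a difference was 0.224 log2 units, and 0.317 for the interaction.

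The alternatives tried were quantile normalization, centring each array on its median, genes above the median level alone, the mean of a gene's probe sets, every probe set on its own, limma's trend and robust settings, array weights, only the 12 arrays of a comparison, an adjusted p under 0.01, a fold of at least 1.5, the replicate number as a block, and each of the 24 arrays left out in turn. Leaving out the 2 arrays least correlated with their groups and adding the poly-A spike-in level as a covariate were chosen after the data were examined. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for preparing tables and for drawing.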

Results

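Expression of 19505 genes was measured on 24 Affymetrix arrays of caecal blind end tissue from C57BL/6JOlaHsd mice, 1 array per mouse. The control diet or a diet supplemented with inulin, a fermentable plant fibre, was fed from 7 weeks of age. Trichuris muris, a whipworm that lives in the caecal epithelium, was given at 9 weeks to 12 of the mice. Tissue was taken 21 days after infection. The 4 groups were control diet uninfected, inulin diet uninfected, control diet infected and inulin diet infected, with 6 mice each, and this number limits the precision. Differences are in log2 units of the deposited scale.

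The groups separated by infection and, among infected mice, by diet. The first principal component held 47.6% of the variance, and its scores were -66.9 to -36 in uninfected mice of both diets, -16.8 to 39.3 in infected mice on the control diet and 75.5 to 115.9 in infected mice on inulin. The second component (11.3%) put infected mice on the control diet at -57.8 to -41.6 and all others at 6.6 to 44.8. Inulin infected replicate 4 correlated least with the other mice of its group (r = 0.9686 across genes, against 0.9863 or more for every other array). It also had the highest poly-A spike-in mean of any array (9.12) and the highest background median (6.54, against 5.1 to 6.04). Inulin uninfected replicate 1 came next, with r = 0.9863. The poly-A spike-in mean was 7.47 to 9.12 in infected mice on inulin and 6.83 to 7.30 in uninfected mice on inulin. On the control diet it was 7.64 to 8.03 in infected replicates 2, 4 and 5, 6.69 to 7.01 in infected replicates 1, 3 and 6, and 6.74 to 7.73 in uninfected mice.

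**Figure D1:**
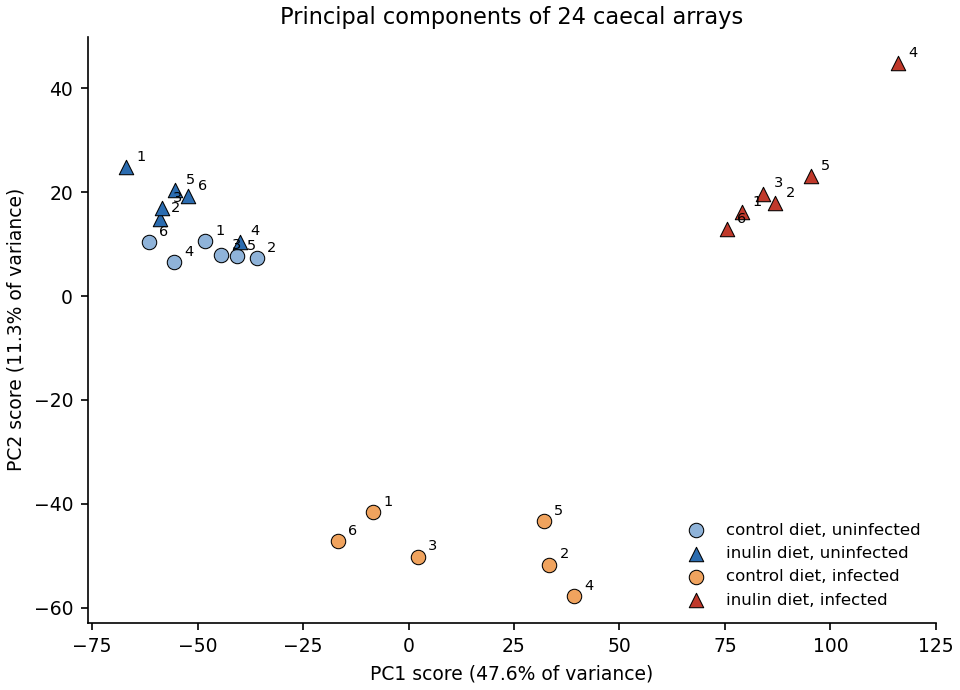
Scores of the 24 arrays on the first 2 principal components of all 19505 genes, with the share of variance on each axis; colour and shape mark the 4 groups and numbers the replicates. Uninfected mice of both diets lie at -66.9 to -36 on the first component, infected mice on the control diet at -16.8 to 39.3 and infected mice on inulin at 75.5 to 115.9, with inulin infected replicate 4 farthest out.

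The first comparison asked what infection changed on the control diet. Mast cell genes had the highest median of the 40 tested lists: 11 of 12 measured members were higher (11 adjusted over the list alone), with a median difference of 5.49 and a camera adjusted p of 4.3e-34, or adjusted p = 0.00015 with an estimated correlation. Mcpt1, a protease of mucosal mast cells, rose from 9.12 ± 0.44 to 18.55 ± 0.20 (SD, n = 6), a difference of 9.43 (SE 0.53, adjusted p = 6e-13). Mcpt2 rose by 9.94 (SE 0.47) and Cpa3 by 9.88 (SE 0.40). Ms4a2 and Fcer1a, which encode subunits of the high-affinity receptor for IgE, rose by 8.75 (SE 0.24) and 8.65 (SE 0.36). Type 2 immunity genes rose with them: 13 of 22 members (15 adjusted over the list alone; camera adjusted p = 1.1e-13, and adjusted p = 0.0085 with an estimated correlation). Il4 rose by 3.70 (SE 0.29) to 7.79 ± 0.40, Il13 by 1.79 (SE 0.27) to 5.86 ± 0.83, Ccl8 by 6.85 (SE 0.55) and Retnla, a product of alternatively activated macrophages and eosinophils, by 6.03 (SE 0.47). Il5 and Il9 differed by 0.02 and 0.07 (adjusted p = 0.97 and 0.9), at group means of 3.86 to 4.03 that lay below the mean of the background probe sets (4.91). Of 9 eosinophil genes 5 rose (6 adjusted over the list alone; camera adjusted p = 1.7e-06, and 8e-04 with an estimated correlation), among them Ccr3 by 5.20 (SE 0.44) and Siglecf by 2.03 (SE 0.32).

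Epithelial defence genes changed on the control diet as well. Of 17 antimicrobial genes 5 rose (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.031 with an estimated correlation). Ang4, an antimicrobial ribonuclease, rose by 6.95 (SE 0.58) to 18.39 ± 0.14 (SD, n = 6), Itln1, a secreted lectin, by 5.39 (SE 0.22) and Retnlb, a goblet cell product, by 4.45 (SE 0.33). Of 19 goblet cell and mucus genes 7 rose and 1 fell (10 and 2 adjusted over the list alone), with Clca1 higher by 1.84 (SE 0.25) and St3gal4 by 5.83 (SE 0.38). The camera adjusted p of this list was 3.2e-05, and adjusted p = 0.15 with an estimated correlation. Muc5ac differed by 0.08 (SE 0.18, adjusted p = 0.84). Of 14 tuft cell genes 3 rose (3 adjusted over the list alone; camera adjusted p = 3.2e-05, and adjusted p = 0.0085 with an estimated correlation): Alox5ap by 3.47 (SE 0.24), Hpgds by 2.04 (SE 0.22) and Avil by 1.55 (SE 0.28). Alox5ap and Hpgds act in leukotriene and prostaglandin synthesis, and mast cells also express them. Of 13 enteroendocrine genes 5 fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.012, and 0.27 with an estimated correlation, or 0.055 over genes above the median level). Chga fell by 1.79 (SE 0.20), and the gene that rose was Tph1, a serotonin synthesis enzyme that mast cells also make, by 4.29 (SE 0.32).

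Large rises on the control diet were also seen for Pla2g4c, a phospholipase, by 11.46 (SE 0.65), for the protease gene Cma2 by 11.03 (SE 0.49) and for Gzma, which encodes granzyme A, by 10.20 (SE 0.47, from 6.26 ± 0.74 to 16.46 ± 1.11, SD, n = 6). Pnliprp2, a pancreatic lipase relative, rose by 9.62 (SE 0.27). Clps, Defa24 and Mptx1, which were chosen after their values were seen, rose by 9.41 (SE 0.34), 7.46 (SE 0.24) and 6.64 (SE 0.44). Of 17 macrophage and monocyte genes 15 rose (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.1e-13, and 0.034 with an estimated correlation), with Itgam higher by 2.73 (SE 0.27) and Adgre1 by 1.92 (SE 0.29). Of 19 cytotoxic lymphocyte genes 6 rose (6 adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.13 with an estimated correlation), among them Gzma, Gzmb by 7.38 (SE 0.65) and Itgae by 3.82 (SE 0.24). Prf1 of the same list overlapped on the control diet, at 4.44 to 5.16 in infected and 4.49 to 4.96 in uninfected mice. Of 11 plasma cell genes 8 rose (9 adjusted over the list alone; camera adjusted p = 5.7e-06, and 0.091 with an estimated correlation), and 3 of 14 T cell genes rose (3 adjusted over the list alone; 0.00051, and adjusted p = 0.27 with an estimated correlation). Of 13 neutrophil genes 3 rose (4 adjusted over the list alone; 0.00098, and 0.13 with an estimated correlation), with Retnlg higher by 5.49 (SE 0.44). Matrix and proliferation genes rose too: 11 of 17 fibroblast genes (16 adjusted over the list alone; 3.6e-10, and 0.013 with an estimated correlation) and 10 of 19 proliferation genes (12 adjusted over the list alone; 9.6e-09, and 0.13 with an estimated correlation). Col3a1 rose by 1.37 (SE 0.28), Sparc by 1.22 (SE 0.18), Mcm3 by 1.49 (SE 0.22) and Mki67 by 0.91 (SE 0.20).

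Interferon-gamma response genes, a list that holds Ifng and Tbx21 beside targets, rose in part on the control diet. Of 28 members 14 passed (19 adjusted over the list alone), with a median of 1.12 and a camera adjusted p of 3e-09, or adjusted p = 0.15 with an estimated correlation. Cxcl9, a chemokine that attracts T cells, rose by 3.30 (SE 0.80, adjusted p = 0.006), and Psmb8, a subunit of the immunoproteasome, by 1.75 (SE 0.34). Ifng itself differed by 0.35 (SE 0.46, adjusted p = 0.71) and Nos2 by 0.88 (SE 0.35, adjusted p = 0.1), and neither passed the threshold. Ido1 did not pass either (adjusted p = 0.17). Without control infected replicate 6, Ido1 passed (adjusted p = 0.031), and Nos2 passed without control uninfected replicate 3 (0.036) or control infected replicate 2 (0.031). None of 19 type I interferon genes passed in limma (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; camera adjusted p = 0.66 and fry adjusted p = 0.83). The infected replicates 2, 4 and 5, which had the higher poly-A level, scored 2.41 to 3.25 above uninfected control mice on the type 2 list and 1.21 to 2.52 on the interferon-gamma list. Replicates 1, 3 and 6 scored 1.32 to 1.89 and 0.25 to 0.73 (mean log2 difference of the members).

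Metabolic genes of the absorptive epithelium fell on the control diet. Of 20 genes for fatty acid oxidation and ketogenesis 19 fell (20 adjusted over the list alone; camera adjusted p = 2.1e-18, and 0.034 with an estimated correlation). Ppara, the receptor that drives these genes, fell by 1.80 (SE 0.22) and Cpt2 fell by 1.13 (SE 0.17). Of 19 xenobiotic metabolism genes 14 fell (14 adjusted over the list alone; 2.8e-09, and 0.034 with an estimated correlation), with Sult1b1 at -1.49 (SE 0.19). Of 21 absorptive colonocyte genes 12 fell and 1 rose (15 and 2 adjusted over the list alone; 7.2e-07, and adjusted p = 0.15 with an estimated correlation), with the sodium transport genes Slc9a3 at -2.87 (SE 0.55) and Scnn1g at -2.65 (SE 0.35). Of 20 oxidative phosphorylation genes 6 fell (13 adjusted over the list alone; 7.2e-07, and 0.091 with an estimated correlation), and 6 of 14 tight junction genes fell (8 adjusted over the list alone; 7.3e-05, and 0.15 with an estimated correlation), with Cldn8 at -2.69 (SE 0.47). Large falls were those of Trpv6, an epithelial calcium channel, at -7.21 (SE 0.45), Cyp4b1 at -6.04 (SE 0.56) and Slc37a2 at -5.59 (SE 0.68). None of 13 smooth muscle genes passed in limma (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; camera adjusted p = 0.11).

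In all, 2709 genes passed the limma threshold on the control diet, 1316 higher and 1393 lower, and 235 of them differed by at least 2 log2 units. The sizes for Cma2, Pnliprp2, Trpv6, Ms4a2, Fcer1a, Il4, Il13, Gzmb and Defa24 are limited by the background, since the lower of their 2 group means (2.87 to 4.31) lay below the mean of the background probe sets (4.91). For Il13 the higher mean (5.86) was also near background, just above the median of those probe sets (5.58). Of the 40 lists 26 passed camera, and 9 of these did so with an estimated correlation.

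**Figure D2:**
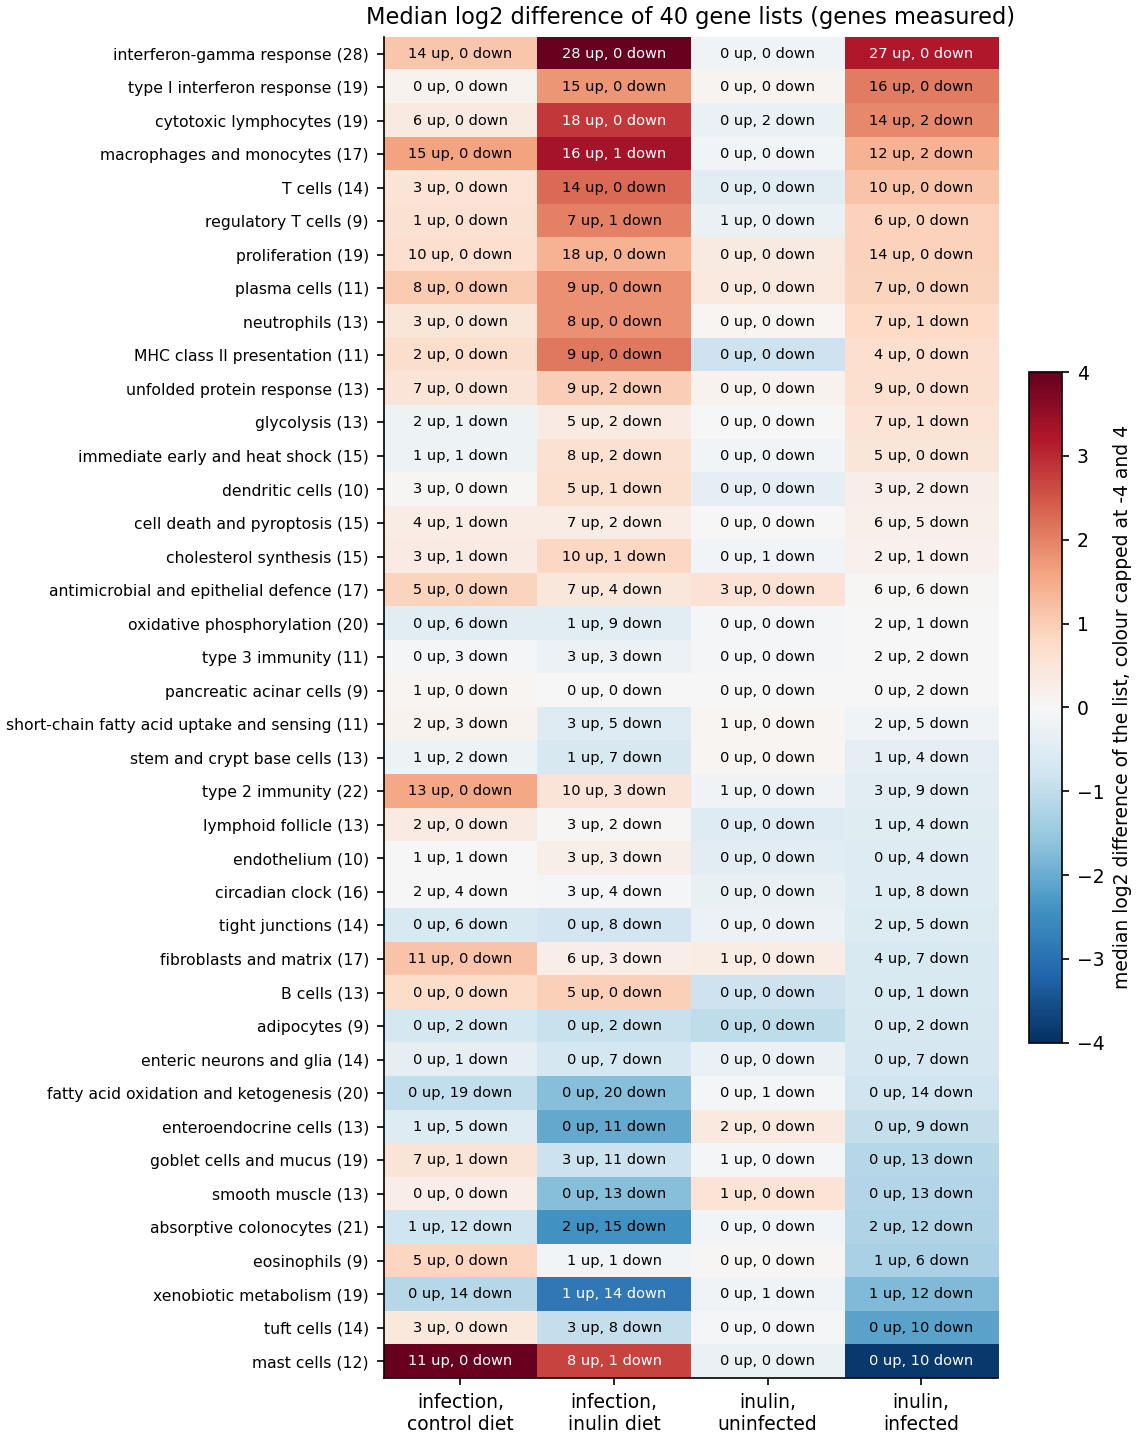
Median log2 difference of 40 gene lists (colour, capped at -4 and 4) in the 4 group comparisons, with the number of members past the limma threshold in each cell and the number measured in brackets. The mast cell list has a median of 5.49 for infection on the control diet and -3.86 for inulin against control diet in infected mice, and the interferon-gamma list has 1.12 and 3.19.

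The second comparison asked what infection changed in mice fed inulin. Interferon-gamma response genes rose: all 28 measured members passed (28 adjusted over the list alone), with a median of 4.58 and a camera adjusted p of 5.3e-28, or 0.04 with an estimated correlation. Cxcl9 rose from 8.47 ± 1.21 to 17.69 ± 0.40 (SD, n = 6), a difference of 9.21 (SE 0.80, adjusted p = 6.7e-10), Cxcl10 by 8.17 (SE 0.62), and Ido1, which degrades tryptophan, by 7.86 (SE 0.69). Ifng rose by 6.35 (SE 0.46) to 10.92 ± 1.39, Nos2, the inducible nitric oxide synthase, by 5.65 (SE 0.35), and Tbx21, the transcription factor of type 1 helper T cells, by 3.11 (SE 0.30). Ubd and Gbp8 rose by 5.43 (SE 0.30) and 5.05 (SE 0.29). Of 19 type I interferon genes 15 rose (15 adjusted over the list alone; camera adjusted p = 1.1e-06, and 0.28 with an estimated correlation). The cytokine genes Il10 and Il22 rose by 2.93 (SE 0.33) and 3.10 (SE 0.43).

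Lymphocyte and myeloid genes rose with them on inulin. Of 19 cytotoxic lymphocyte genes 18 rose (18 adjusted over the list alone; camera adjusted p = 2.7e-16, and 0.013 with an estimated correlation): Gzma by 8.91 (SE 0.47), Gzmb by 8.26 (SE 0.65), Ccl5 by 6.02 (SE 0.35), Nkg7 by 5.51 (SE 0.32) and Cd8a by 3.86 (SE 0.24). All 14 T cell genes rose (14 adjusted over the list alone; 3.6e-10, and 0.08 with an estimated correlation). Of 17 macrophage and monocyte genes 16 rose and 1 fell (16 and 1 adjusted over the list alone; 2.2e-13, and 0.062 with an estimated correlation), with Fcgr1 higher by 5.17 (SE 0.40) and C1qa by 3.78 (SE 0.27). MHC class II genes rose in 9 of 11 (9 adjusted over the list alone; 4.5e-06, and adjusted p = 0.21 with an estimated correlation). Neutrophil genes rose in 8 of 13 (9 adjusted over the list alone; 3e-05, and 0.08 with an estimated correlation) and proliferation genes in 18 of 19 (18 adjusted over the list alone; 1.7e-10, and 0.093 with an estimated correlation), with Top2a higher by 2.21 (SE 0.24). Reg3b and Reg3g, antimicrobial lectins of the epithelium, rose by 7.46 (SE 0.96) and 5.63 (SE 0.83), in an antimicrobial list with 7 of 17 higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.12). The matrix genes Mmp10 and Timp1 rose by 5.80 (SE 0.52) and 4.73 (SE 0.43), while of 17 fibroblast and matrix genes 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.18). Pfkfb3, a glycolysis regulator, rose by 2.88 (SE 0.22), in a glycolysis list of 13 with 5 higher and 2 lower (6 and 2 adjusted over the list alone; 0.02, and adjusted p = 0.35 with an estimated correlation).

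Type 2 genes on inulin split. Mcpt1 and Mcpt2 rose by 6.42 (SE 0.53) and 5.84 (SE 0.47), in a mast cell list with 8 of 12 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 1.5e-05, and 0.099 with an estimated correlation). Of 22 type 2 genes 10 rose and 3 fell (10 and 4 adjusted over the list alone; 0.021, and adjusted p = 0.35 with an estimated correlation). With the poly-A level as a covariate that camera p was 0.056, and over genes above the median level 0.07. Retnla fell by 6.54 (SE 0.47) from 10.39 ± 0.34 to 3.85 ± 1.26 (SD, n = 6), below the mean of the background probe sets. Arg1, an arginase, rose by 3.74 (SE 0.65), while Il4 and Il13 differed by 0.28 (SE 0.29, adjusted p = 0.49) and 0.52 (SE 0.27, adjusted p = 0.14). Il13 passed when only the 12 arrays on inulin were fitted (adjusted p = 0.048). Retnlb differed by 0.38 (SE 0.33, adjusted p = 0.4) and passed without inulin infected replicate 5 (0.047).

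Epithelial and muscle genes fell on inulin. Cyp2c55, an abundant cytochrome of the large intestine, fell by 8.30 (SE 0.28) from 18.41 ± 0.09 to 10.11 ± 0.77 (SD, n = 6). Of 21 absorptive colonocyte genes 15 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 3.2e-08, and adjusted p = 0.12 with an estimated correlation), with Car4 at -5.00 (SE 0.34) and Scnn1g at -4.13 (SE 0.35). All 20 fatty acid oxidation genes fell (20 adjusted over the list alone; 4.7e-14, and 0.08 with an estimated correlation), with Acadm at -2.51 (SE 0.19), and 14 of 19 xenobiotic metabolism genes fell while 1 rose (14 and 1 adjusted over the list alone; 2.8e-09, and 0.062 with an estimated correlation). Of 13 enteroendocrine genes 11 fell (11 adjusted over the list alone; 3.2e-08, and 0.062 with an estimated correlation), with Gcg, the glucagon-like peptide precursor, at -5.22 (SE 0.34) and Chga at -2.58 (SE 0.20). Tuft cell genes fell in 8 of 14 and rose in 3 (8 and 3 adjusted over the list alone; 0.014, and 0.093 with an estimated correlation), with Dclk1 at -1.86 (SE 0.19) and Gnat3 at -3.61 (SE 0.26). Of 19 goblet cell genes 11 fell and 3 rose (13 and 3 adjusted over the list alone; 0.002, and adjusted p = 0.28 with an estimated correlation). Inulin infected replicate 4 scored -1.39 on this list, against -0.73 to -0.23 for the other mice of its group. Tff3 fell by 1.97 (SE 0.14) and Clca1 fell by 1.47 (SE 0.25), while St3gal4 rose by 6.26 (SE 0.38).

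All 13 smooth muscle genes fell on inulin (13 adjusted over the list alone; camera adjusted p = 1.3e-08, and adjusted p = 0.12 with an estimated correlation). Actg2, a contractile actin of the gut, fell by 3.83 (SE 0.27) from 17.19 ± 0.13 to 13.36 ± 0.85 (SD, n = 6), Cnn1 fell by 3.59 (SE 0.24) and Myh11 fell by 2.27 (SE 0.24). Enteric neuron and glia genes, which mark another cell type of the muscle wall, fell in 7 of 14 (7 adjusted over the list alone; median -0.70, camera adjusted p = 0.003, and adjusted p = 0.12 with an estimated correlation). Of 13 stem and crypt base genes 7 fell and 1 rose (7 and 2 adjusted over the list alone; 0.02, and adjusted p = 0.37 with an estimated correlation), with Lgr5, a stem cell marker, at -2.39 (SE 0.40). That camera p was 0.071 over genes above the median level, 0.059 without the 2 arrays least correlated with their groups and 0.23 with the poly-A level as a covariate. Of 14 tight junction genes 8 fell (10 adjusted over the list alone; 0.0021, and adjusted p = 0.28 with an estimated correlation), with Cldn8 at -5.62 (SE 0.47). Large falls were those of Slc37a2 at -8.82 (SE 0.68), Slc30a10 at -8.78 (SE 0.47), Trpm6 at -8.66 (SE 0.63) and Ces1g at -8.63 (SE 0.47).

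On inulin 7500 genes passed the limma threshold, 3496 higher and 4004 lower, and 1233 of them differed by at least 2 log2 units. Which direction held more genes depended on the scaling: 4177 were higher and 3372 lower when each array was centred on its median, and 3830 and 3790 after quantile normalization. The same background limit held for Slc30a10, Ubd, Ifng, Tbx21, Il10, Il22, Retnla, Arg1, Gnat3, Scnn1g, Mmp10 and Cldn8 (lower means of 2.77 to 4.86). For Il22 the higher mean (5.88) was also near the median of the background probe sets (5.58). Of the 40 lists 28 passed camera, and 2 of these did so with an estimated correlation. The poly-A level and infection moved together here (7.47 to 9.12 against 6.83 to 7.30), and 5398 genes passed with that level as a covariate, 5071 of them among the 7500. When each array was centred on its median, the median of all genes moved by 0.108, and by 0.129 and 0.136 in the comparison of diets under infection and in the interaction.

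The third comparison asked what inulin changed without infection. The epithelial genes Cyp4f15, a fatty acid hydroxylase, and Igfbp2, a binder of insulin-like growth factors, rose by 3.75 (SE 0.26, adjusted p = 1.3e-09) and 3.56 (SE 0.32); Igfbp2 went from 7.37 ± 0.32 to 10.92 ± 0.67 (SD, n = 6). Slc5a8, a transporter of short-chain fatty acids, rose by 2.73 (SE 0.33, adjusted p = 2.7e-05) from 12.46 ± 0.54 to 15.20 ± 0.28. Gut hormone genes rose as well: Nts, the neurotensin gene, by 2.33 (SE 0.24) and Gcg by 1.72 (SE 0.34), which were 2 of 13 enteroendocrine genes (5 adjusted over the list alone; camera adjusted p = 3.3e-05, and adjusted p = 0.19 with an estimated correlation). Ces2a, a carboxylesterase, fell by 3.47 (SE 0.52), and Insig1, a regulator of sterol synthesis, fell by 1.98 (SE 0.20). In each of these 7 genes the 6 mice on inulin lay apart from the 6 on the control diet.

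Other genes that rose with inulin were Ak4 by 2.42 (SE 0.32), Pla2g3 by 2.35 (SE 0.36), Saa1 by 2.13 (SE 0.43, adjusted p = 0.0095) and Actg2 by 1.31 (SE 0.27, adjusted p = 0.012). Retnla, chosen after its values were seen, rose by 2.24 (SE 0.47, adjusted p = 0.015). Ly6g6c, B3galt5 and Creb3l3 fell, at -2.34 (SE 0.32), -2.29 (SE 0.43) and -2.02 (SE 0.35), and Hsd17b14 fell as well. Of 17 antimicrobial genes 3 rose, namely Saa1, Duoxa2 and Lcn2 (4 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.19 with an estimated correlation), and of 11 genes for uptake and sensing of short-chain fatty acids 1 rose (2 adjusted over the list alone; 0.073), which was Slc5a8. Ffar2 and Slc16a1 differed by 0.40 (adjusted p = 0.76) and 0.46 (adjusted p = 0.64). Smooth muscle genes had a median of 0.55 with 1 of 13 past the threshold (5 adjusted over the list alone; 4.3e-07, and adjusted p = 0.34 with an estimated correlation).

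Many immune and mucus genes did not pass the threshold for diet without infection. Il4 differed by 0.16 (adjusted p = 0.89), Il13 by -0.14 (0.91), Ifng by -0.34 (0.85), Retnlb by -0.40 (0.73), Muc2 by -0.10 (0.93), Ido1 by -0.28 (0.93), Nos2 by 1.00 (0.24) and Reg3g by 1.27 (0.61). Mcpt1 differed by -1.08 (SE 0.53, adjusted p = 0.46) and passed when arrays were weighted (adjusted p = 0.049). None of 11 MHC class II genes passed in limma (7 lower adjusted over the list alone, 8 at an unadjusted p under 0.05; camera adjusted p = 2.8e-05, and adjusted p = 0.34 with an estimated correlation; fry adjusted p = 0.2), and none of 13 B cell genes passed (0 adjusted over the list alone, 4 at an unadjusted p under 0.05; 1.9e-06, and adjusted p = 0.34 with an estimated correlation; fry adjusted p = 0.2). Inulin uninfected replicate 1 scored -2.86 on the B cell list and -2.42 on the MHC class II list, against -0.95 to 0.39 and -0.99 to 0.35 for the other 5. The endothelium list was lower and was the only 1 of 18 called lists that held with an estimated correlation (median -0.46, camera adjusted p = 0.00014, and 0.017 with an estimated correlation), although 0 of 10 members passed in limma (1 lower adjusted over the list alone, 5 at an unadjusted p under 0.05; fry adjusted p = 0.0021).

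Without infection 142 genes passed the limma threshold for diet, 105 higher and 37 lower, out of 2198 at an unadjusted p under 0.05. The count was 90 without inulin uninfected replicate 5, 92 without control uninfected replicate 3 and 274 without inulin infected replicate 4, and it was 570 with array weights and 365 when only the 12 uninfected arrays were fitted.

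The fourth comparison asked how infected mice on inulin differed from infected mice on the control diet. Interferon-gamma response genes were higher on inulin in 27 of 28 (27 adjusted over the list alone), with a median of 3.19 and a camera adjusted p of 5.4e-33, or 0.013 with an estimated correlation. Ifng was higher by 5.67 (SE 0.46, adjusted p = 4.8e-10; 5.26 ± 0.78 and 10.92 ± 1.39, SD, n = 6). Mast cell genes were lower in 10 of 12 (10 adjusted over the list alone), with a median of -3.86 and a camera adjusted p of 4.9e-15, or 0.0099 with an estimated correlation. Il4 was lower, at -3.26 (SE 0.29, adjusted p = 2.5e-09; 7.79 ± 0.40 and 4.53 ± 0.54), with no overlap between the 6 and 6 mice for Ifng or Il4. Retnla differed by -10.33 (SE 0.47; 14.18 ± 0.80 and 3.85 ± 1.26).

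Among the interferon-gamma targets Ido1 was higher by 6.07 (SE 0.69), Cxcl10 by 6.02 (SE 0.62), Nos2 by 5.78 (SE 0.35), Cxcl9 by 5.77 (SE 0.80), Ubd by 4.51 (SE 0.30) and Gbp8 by 3.65 (SE 0.29). Type I interferon genes were higher in 16 of 19 (19 adjusted over the list alone; camera adjusted p = 3.9e-11, and adjusted p = 0.11 with an estimated correlation). Of 19 cytotoxic lymphocyte genes 14 were higher and 2 lower (16 and 2 adjusted over the list alone; 1.1e-11, and 0.013 with an estimated correlation): Prf1, the perforin gene, by 3.31 (SE 0.22) and Ccl5 by 4.63 (SE 0.35), against Itgae at -2.90 (SE 0.24) and Gzma, the 2 that were lower. Tbx21 was higher by 2.40 (SE 0.30), Il10 by 2.05 (SE 0.33), Il22 by 2.32 (SE 0.43) and Il33, an epithelial alarm cytokine, by 1.16 (SE 0.27, adjusted p = 0.002). Of 17 macrophage and monocyte genes 12 were higher and 2 lower (14 and 2 adjusted over the list alone; 1.5e-07, and adjusted p = 0.11 with an estimated correlation), with Fcgr1 higher by 3.82 (SE 0.40) and Ly6c2 by 3.48 (SE 0.37). T cell genes were higher in 10 of 14 (10 adjusted over the list alone; 2.5e-06, and 0.12 with an estimated correlation) and proliferation genes in 14 of 19 (16 adjusted over the list alone; 7.8e-11, and 0.096 with an estimated correlation). Other large rises were those of Reg3b by 6.56 (SE 0.96), Upp1, a uridine phosphorylase, by 6.44 (SE 0.30), and Clca4b by 5.95 (SE 0.44). Reg3g and Lcn2 were higher by 5.12 (SE 0.83) and 4.14 (SE 0.30), in an antimicrobial list with 6 of 17 higher and 6 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.9).

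On the type 2 side, Ms4a2 was lower on inulin, at -6.03 (SE 0.24), Fcer1a at -6.29 (SE 0.36), Kit, the stem cell factor receptor of mast cells, at -3.66 (SE 0.21), Mcpt2 at -4.59 (SE 0.47) and Mcpt1 at -4.09 (SE 0.53). Of 22 type 2 genes 9 were lower and 3 higher (9 and 3 adjusted over the list alone; camera adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation), and that camera p was 0.6 over genes above the median level and 0.067 without control infected replicate 4. Il13 was lower, at -1.41 (SE 0.27), while Arg1 differed by 0.53 (SE 0.65, adjusted p = 0.63). Of 9 eosinophil genes 6 were lower and 1 higher (6 and 1 adjusted over the list alone; 0.00077, and 0.013 with an estimated correlation), with Ccr3 at -3.89 (SE 0.44) and Siglecf at -2.71 (SE 0.32). Goblet cell genes were lower in 13 of 19 (13 lower and 1 higher adjusted over the list alone; 1.6e-11, and 0.028 with an estimated correlation): Retnlb at -4.47 (SE 0.33), Clca1 at -3.24 (SE 0.25), Spink4 at -3.07 (SE 0.19) and Muc2, the main mucin of the gut, at -1.13 (SE 0.24). Tuft cell genes were lower in 10 of 14 (11 adjusted over the list alone; 1.6e-11, and 0.00015 with an estimated correlation), with Dclk1 at -2.79 (SE 0.19) and Gnat3 at -3.58 (SE 0.26). Clps, Mptx1, Pnliprp2, Rnase2a and Defa24 differed by -9.76 (SE 0.34), -8.85 (SE 0.44), -8.77 (SE 0.27), -8.11 (SE 0.35) and -7.70 (SE 0.24). In infected mice on inulin their means were 2.63 to 4.97, at or near the mean of the background probe sets.

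Absorptive and muscle genes were also lower in infected mice on inulin. Cyp2c55 was lower, at -7.48 (SE 0.28) and Car4 at -3.34 (SE 0.34), in a colonocyte list with 12 of 21 lower and 2 higher (14 and 2 adjusted over the list alone; camera adjusted p = 2e-07, and adjusted p = 0.11 with an estimated correlation). Xenobiotic metabolism genes were lower in 12 of 19 and higher in 1 (12 and 1 adjusted over the list alone; 5e-10, and 0.032 with an estimated correlation). Fatty acid oxidation genes were lower in 14 of 20 (16 adjusted over the list alone; 1e-08, and 0.11 with an estimated correlation) and enteroendocrine genes lower in 9 of 13 (9 adjusted over the list alone; 2e-05, and 0.096 with an estimated correlation), with Tph1 at -5.50 (SE 0.32). All 13 smooth muscle genes were lower (13 adjusted over the list alone; 7.8e-11, and 0.097 with an estimated correlation), with Cnn1 at -3.16 (SE 0.24), Actg2 at -3.11 (SE 0.27) and Myh11 at -2.19 (SE 0.24). Genes of other cell types of the wall were lower as well. Enteric neuron and glia genes were lower in 7 of 14 (8 adjusted over the list alone, median -0.66, camera adjusted p = 0.00014, and 0.082 with an estimated correlation). So were endothelium genes in 4 of 10 (6 adjusted over the list alone; 0.034, and 0.1 with an estimated correlation) and adipocyte genes in 2 of 9 (4 adjusted over the list alone; 0.036, and adjusted p = 0.38 with an estimated correlation). The endothelium call was lost, at 0.053 to 0.06, without control infected replicate 2 or 4 or inulin infected replicate 4. It was also lost, at 0.057 to 0.13, with quantile normalization, the poly-A covariate or genes above the median level. The adipocyte call was lost, at 0.056 to 0.086, without control infected replicate 4, 5 or 6 or inulin infected replicate 3 or 5. Endothelium scores on inulin were alike without infection (-0.60 to -0.21) and with it (-0.61 to -0.28), so this difference was not particular to infected mice. Adipocyte scores without infection were -1.91 to -0.03 on inulin and -1.03 to 0.99 on the control diet. Smooth muscle scores on inulin were 0.36 to 0.84 without infection and -1.90 to -0.13 with it. Inulin infected replicate 4, the array with the highest poly-A level and background, scored -0.13 on the smooth muscle list, against -1.90 to -1.19 for the other 5 of its group.

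Under infection 4525 genes passed the limma threshold for diet, 2029 higher and 2496 lower, and 505 of them differed by at least 2 log2 units. The background limit held for Retnla, Il4, Il13, Mptx1, Pnliprp2, Rnase2a, Defa24, Nos2, Tbx21, Gnat3, Prf1 and Il22 (lower means of 2.63 to 4.89). Ifng in infected mice on the control diet lay above the mean of the background probe sets but below their median (5.58). The higher means of Il13 (5.86) and Il22 (5.88) lay just above that median. Of the 40 lists 29 passed camera, and 7 of these did so with an estimated correlation. When each array was centred on its median, 2881 were higher and 1866 lower, so the share of higher genes went from 44.8% to 60.7%. The poly-A mean was 6.69 to 8.03 on the control diet and 7.47 to 9.12 on inulin, and 3434 genes passed with it as a covariate, 3215 of them among the 4525.

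**Figure D3:**
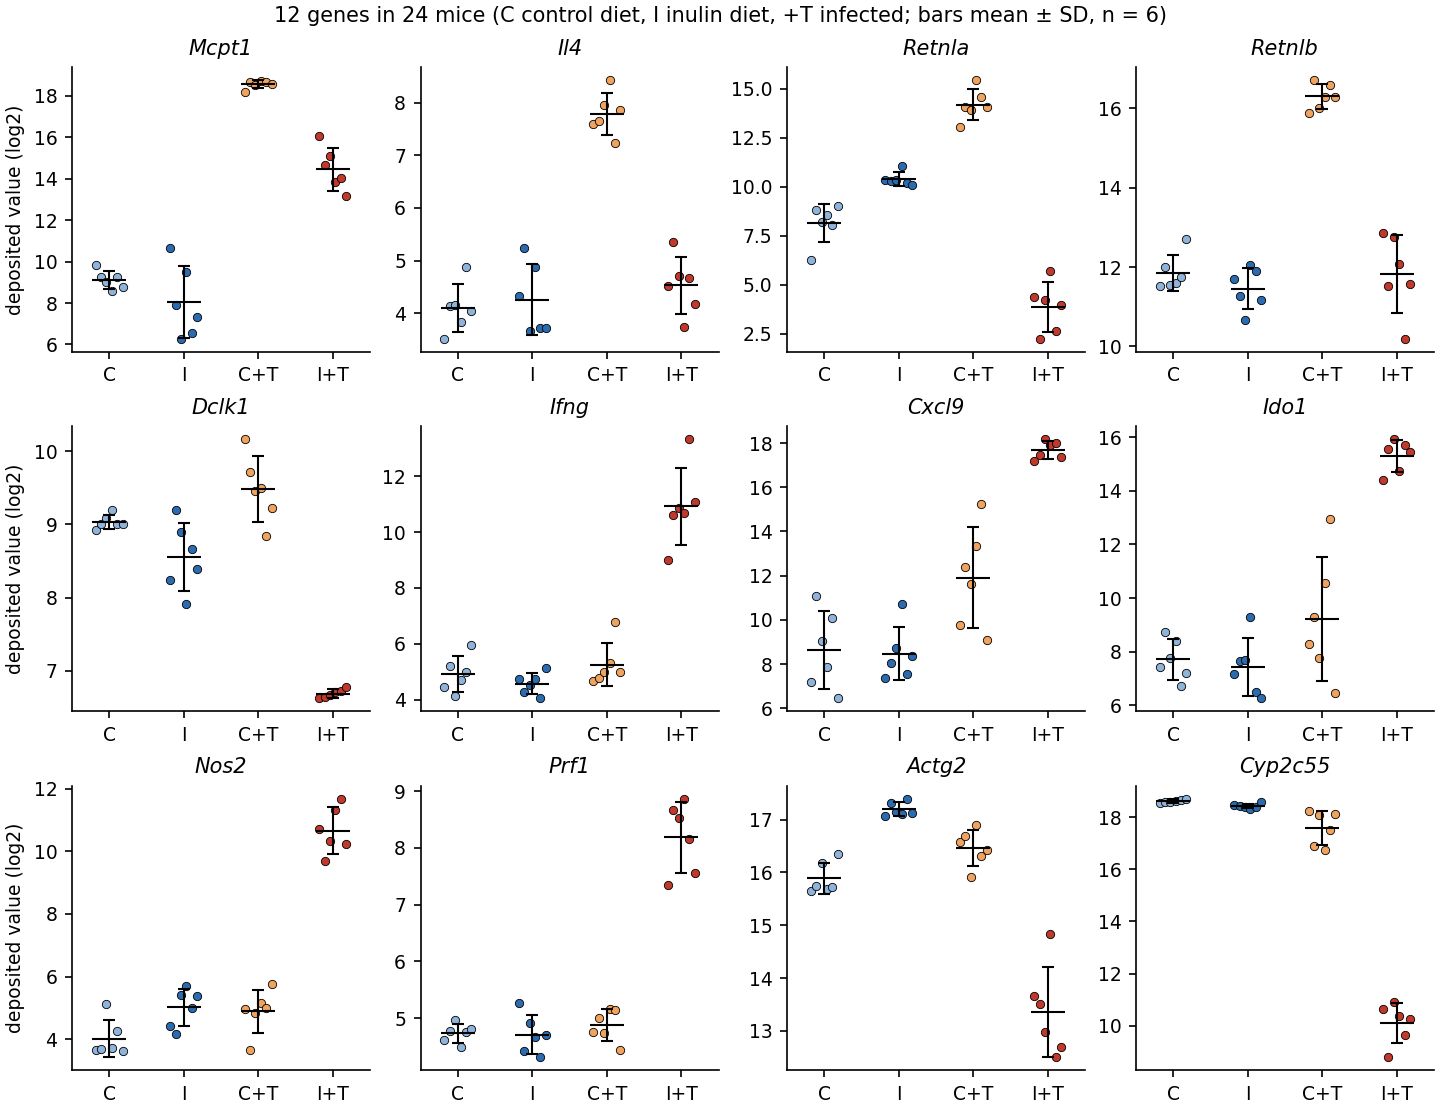
Deposited log2 values of 12 genes in the 24 mice (points), with the mean and SD of the 6 mice of each group: C control diet, I inulin diet, and +T infected. Mcpt1, Il4, Retnla, Retnlb and Dclk1 are lower, and Ifng, Cxcl9, Ido1, Nos2 and Prf1 higher, in infected mice on inulin than in infected mice on the control diet; Actg2 and Cyp2c55 are lower there, at 13.36 ± 0.85 and 10.11 ± 0.77.

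The interaction tested whether the response to infection differed between diets. Retnla went opposite ways, up by 6.03 (SE 0.47) on the control diet and down on inulin at -6.54 (SE 0.47), with an interaction of -12.57 (SE 0.67, adjusted p = 5e-13; group means from n = 6). Clca1 also rose on the control diet and fell on inulin, with an interaction of -3.31 (SE 0.35). Tph1 did the same, at 4.29 (SE 0.32) and -2.14 (SE 0.32), with an interaction of -6.43 (SE 0.45). Interferon-gamma response genes responded more on inulin in 27 of 28 (28 adjusted over the list alone, camera adjusted p = 1.2e-33, and 0.009 with an estimated correlation). Among them were Ido1 by 6.36 (SE 0.98), Cxcl10 by 6.23 (SE 0.88), Ifng itself by 6.00 (SE 0.64), Cxcl9 by 5.92 (SE 1.14), Ubd by 5.13 (SE 0.42) and Nos2 by 4.78 (SE 0.49). Upp1 and Clca4b had interactions of 6.78 (SE 0.43) and 5.87 (SE 0.62).

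Cytotoxic lymphocyte genes responded more on inulin in 14 of 19 and less in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 1.1e-13, and 0.009 with an estimated correlation), with Nkg7 at 4.80 (SE 0.45) and Prf1 at 3.33 (SE 0.31). T cell genes did so in 10 of 14 (12 adjusted over the list alone; 2.9e-09, and 0.1 with an estimated correlation). Mast cell genes had negative interactions in 10 of 12 (10 adjusted over the list alone; 3.8e-14, and 0.009 with an estimated correlation), with Fcer1a at -6.05 (SE 0.51) and Ms4a2 at -5.54 (SE 0.33). Il4 stood at -3.43 (SE 0.40) and Il13 at -1.27 (SE 0.39, adjusted p = 0.026); centring on the array median ended the call of Il13 (adjusted p = 0.063). The type 2 list had 6 of 22 negative and 4 positive (6 and 4 adjusted over the list alone; 0.025, and adjusted p = 0.35 with an estimated correlation), with a camera p of 0.41 over genes above the median level, 0.13 without control infected replicate 4 and 0.05 without control infected replicate 5. Eosinophil genes were negative in 4 of 9 and positive in 1 (5 and 1 adjusted over the list alone; 0.002, and 0.02 with an estimated correlation). Goblet cell genes were negative in 13 of 19 (14 adjusted over the list alone; 5.1e-12, and 0.024 with an estimated correlation), with Retnlb at -4.07 (SE 0.47), and tuft cell genes in 10 of 14, with 1 positive (10 and 1 adjusted over the list alone; 5.3e-10, and 0.00045 with an estimated correlation), with Gnat3 at -3.93 (SE 0.37) and Dclk1 at -2.31 (SE 0.27).

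Smooth muscle genes had negative interactions in 12 of 13 (13 adjusted over the list alone; camera adjusted p = 3.8e-14, and 0.06 with an estimated correlation), with Actg2 at -4.41 (SE 0.37) and Cnn1 at -4.15 (SE 0.34). Colonocyte genes were negative in 12 of 21 and positive in 1 (13 and 1 adjusted over the list alone; 5e-06, and adjusted p = 0.22 with an estimated correlation), with Cyp2c55 at -7.28 (SE 0.39) and Car4 at -4.22 (SE 0.48). Enteroendocrine genes were negative in 8 of 13 (9 adjusted over the list alone; 1.8e-08, and 0.028 with an estimated correlation), with Gcg at -4.02 (SE 0.48). Slc5a8, which inulin had raised without infection, stood at -2.84 (SE 0.47). Clps, Pnliprp2, Rnase2a, Mptx1 and Defa24 had interactions of -9.78 (SE 0.48), -9.19 (SE 0.39), -8.90 (SE 0.50), -7.78 (SE 0.62) and -7.57 (SE 0.33).

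The interaction passed the limma threshold in 2737 genes, 1096 positive and 1641 negative. With each array centred on its median these were 1541 and 1260, so the share of positive genes went from 40% to 55%. Interactions of genes with a group mean below the background mean are limited in size in the same way. Of the 40 lists 27 passed camera, and 7 of these did so with an estimated correlation.

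Across genes the responses to infection on the 2 diets correlated at r = 0.62 (jackknife SE 0.061, Spearman's rho 0.572), where genes are not independent replicates. Of 1316 genes that rose on the control diet 926 also rose on inulin, against 236 by chance, and 70 fell; of 1393 that fell, 1163 also fell, against 286 by chance, and 4 rose. The diet effects without and under infection correlated at r = -0.011 (SE 0.076, rho -0.007). Of the 105 genes that inulin raised without infection 13 were also higher under infection, against 10.9 by chance, and 29 were lower. Of the 37 that it lowered, 13 were also lower, against 4.73 by chance, and 7 were higher. The chance numbers are for genes that moved the same way, and none was computed for those that went the opposite way.

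**Figure D4:**
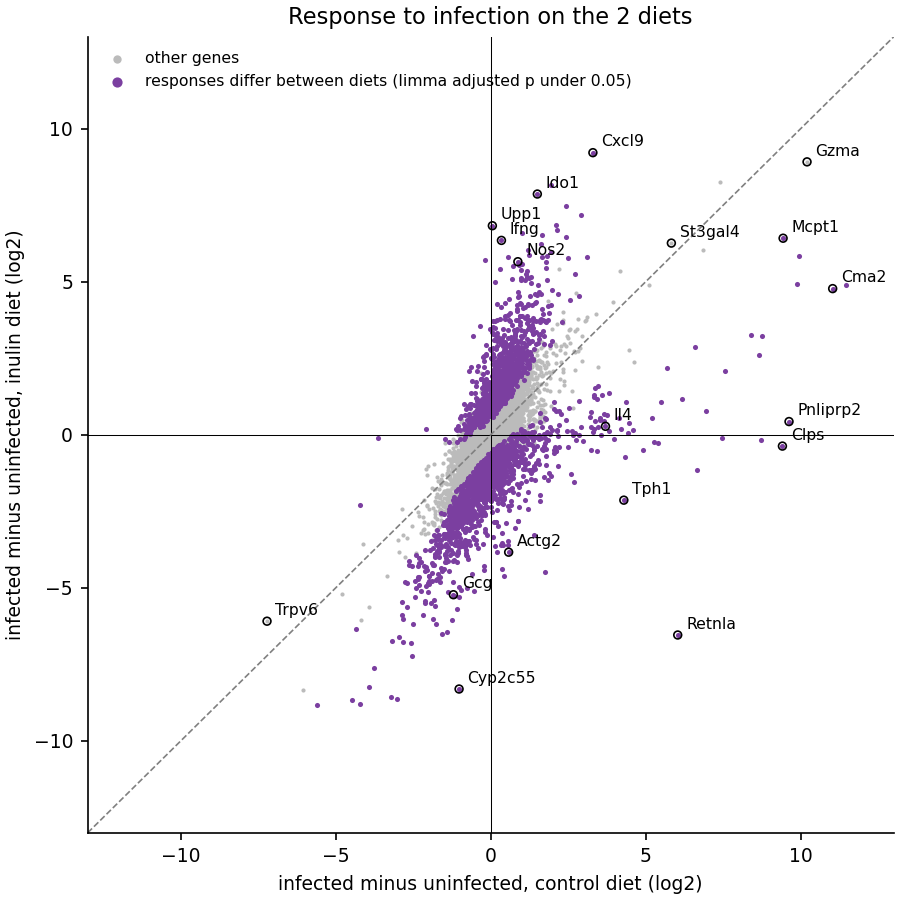
Response to infection of 19505 genes on the control diet (horizontal) and on inulin (vertical), as infected minus uninfected log2 differences, with the line of equality dashed. Purple points are the 2737 genes whose responses differed between diets at a limma adjusted p under 0.05; Retnla lies at 6.03 and -6.54, and Ifng at 0.35 and 6.35.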

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

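The tests for pancreatic tissue and for 1 array with another tissue mixture, and the tests of Paneth cell products and of further muscle layer genes, were chosen after the result was seen; the small intestinal list was added after the data were examined, before its own values were seen.

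Each of 115 genes in each group, and 4 array measures per group, were searched for 1 array far from the other 5 (a gap to the nearest array that takes up most of the range of the group). Of 476 sets 38 had such an array, where chance would give about 24 (1 in 20), and 16 of the 38 were on inulin infected replicate 4. On that array Adgre1 (8.25), Ccl8 (12.53), Ccr3 (5.59), Gzma (13.04), Kit (8.93), Lgr5 (4.61), Muc2 (16.16), Pla2g4c (8.01), Retnlg (8.57), Slc16a1 (11.58), St3gal4 (11.59) and Tph1 (6.59) were the lowest of the group, and Tbx21 (8.25) was the highest. Its background median (6.54) and poly-A spike-in mean (9.12) were the highest, and its correlation with the group (0.9686) was the lowest. In infected mice on inulin, Il33 (9.85) and Il5 (3.73) were lowest in replicate 1 and Ccl5 (12.86) in replicate 6. In infected mice on the control diet, Lcn2 (9.04) was highest and the correlation with the group (0.9878) lowest in replicate 4. Ifng (6.79) and Ubd (6.45) were highest in replicate 5, Mcpt1 (18.16) was lowest in replicate 1 and Retnlg (16.14) was highest in replicate 3.

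In uninfected mice on the control diet, replicate 2 was apart for Ang4 (13.94, highest), Cyp4b1 (12.88, lowest) and St3gal4 (9.35, highest). Replicate 6 was apart for Cd8a (8.57, lowest), Slc16a1 (16.37, highest) and Hpgds (9.34, lowest), replicate 3 for Il22 (3.86, highest) and replicate 1 for Retnla (6.27, lowest). In uninfected mice on inulin, replicate 1 was apart for Il5 (5.04, highest) and Itln1 (6.67, highest), replicate 2 for Car4 (14.40, lowest), replicate 3 for Sparc (14.67, lowest) and replicate 4 for Retnla (11.05, highest).

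Inulin infected replicate 4 was weighed against a wrong label and against poorer RNA or hybridization. A mislabelled sample is argued against, because its correlation with the mean of any other group was at most 0.9461, against 0.9686 with its own (a difference of -0.0225). Poorer RNA or hybridization cannot be told apart from a difference of the mouse. The deviation of the array from its group ran against the gene level at r = -0.297, outside the -0.176 to 0.174 of the other arrays, and its poly-A mean and background (9.12 and 6.54, against at most 8.03 and 6.04 elsewhere) lay on the same side. A single mouse with such a difference in tissue state stays open, and no measure of RNA quality was used here.

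Responses to infection differed between diets in 2737 genes, by a test of the interaction. The named genes with positive interactions were Upp1 (6.78), Ido1 (6.36), Cxcl10 (6.23), Ifng (6.00), Cxcl9 (5.92), Clca4b (5.87), Ubd (5.13), Nkg7 (4.80), Nos2 (4.78) and Prf1 (3.33). A negative interaction can be a smaller rise or a deeper fall on inulin, and the named genes with one were Retnla (-12.57), Clps (-9.78), Pnliprp2 (-9.19), Rnase2a (-8.90), Mptx1 (-7.78), Defa24 (-7.57), Cyp2c55 (-7.28), Tph1 (-6.43), Fcer1a (-6.05), Ms4a2 (-5.54), Actg2 (-4.41), Car4 (-4.22), Cnn1 (-4.15), Retnlb (-4.07), Gcg (-4.02), Gnat3 (-3.93), Il4 (-3.43), Clca1 (-3.31), Slc5a8 (-2.84), Dclk1 (-2.31) and Il13 (-1.27). These include the largest rises and falls, so they were partly chosen for their size.

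The counts of changed genes were set beside 100 groupings of the same arrays, the real one included, and only the real grouping reached its count in each of the 5 comparisons. The highest count of the others was 14 against 2709 for infection on the control diet, 4076 against 7500 for infection on inulin, 61 against 142 for diet without infection and 1960 against 4525 for diet under infection. For the interaction, where residuals were reassigned, it was 210 against 2737. Each share was 1 in 100, which is the lowest that 100 groupings can give. The real counts were thus above those of the groupings drawn, and no smaller share can be stated.

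Clps, Pnliprp2, Defa24, Itln1 and Mptx1 rose in infected mice on the control diet and not on inulin, and they are genes that pancreas or small intestine express. Pancreatic tissue in the samples is argued against: 8 other acinar genes had a median of 0.06 (range -0.59 to 0.53), and none passed in limma (4 of 9 at an unadjusted p under 0.05 when Clps is counted). Small intestinal tissue is argued against as well: the 19 small intestinal enterocyte genes, 1 of which is also in another list, had a median of -0.29, with 1 higher and 2 lower. Of 18 Paneth cell products 12 rose on the control diet, but this list was written after Defa24, Itln1 and Mptx1 were seen to rise. The list was also cut to the 5 members that share no symbol stem with these genes or with list members that other lists also hold. Of these 5, 1 rose, which was Nupr1 (2 adjusted over the list alone, median 0.14, camera adjusted p = 0.34). Guca2b, Mmp7 and Reg3a of the 5 still share a stem with genes of other lists. The source of the rise stays open.

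Smooth muscle genes were lower in infected mice on inulin than on the control diet, in 13 of 13. A smaller share of muscle layer in the tissue was predicted to lower them alike. The log2 differences of the 10 members with a mean of 10 or more had an SD of 0.901 against a median SE of 0.245 (ratio 3.67). The prediction holds only if no other cells express these genes and the deposited scale is even across levels. Neither was tested, so the unequal falls cannot decide for or against a smaller share. A smaller share stays open as a part or the whole of the difference, since enteric neuron and glia genes, which lie in the same layer, were lower too: 7 of 14, with 0 higher in limma (8 lower adjusted over the list alone, 9 at an unadjusted p under 0.05; fry adjusted p = 9e-06), all 14 below 0 (-2.13 to -0.12), a median of -0.66 and a camera adjusted p of 0.00014, or 0.082 with an estimated correlation. One array with another tissue mixture is argued against, since at least 11 of 13 stayed lower whichever of the 12 infected arrays was left out. Of 22 further muscle layer genes 15 were lower and 0 higher in limma (16 adjusted over the list alone, 17 at an unadjusted p under 0.05; fry adjusted p = 2.7e-07), with a median of -1.18 (camera adjusted p = 1.4e-12, and 0.024 with an estimated correlation), and a lower expression of contractile genes per muscle cell may contribute, alone or beside a smaller share.

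Probe sets without a gene symbol are outside the comparisons of the report, and 2634 were measured. Of these 128 were higher with infection on the control diet, 402 with infection on inulin, 6 with inulin without infection and 224 with inulin under infection. In all 241, 756, 6 and 453 of them differed.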

How the results depend on the processing

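Leaving out the 2 arrays least correlated with their groups, and adding the poly-A level as a covariate, were chosen after the result was seen. No named gene and no list past its threshold changed direction under the alternatives run. For the other genes only counts were followed. The balance of higher and lower genes did turn with centring, from 3496 and 4004 to 4177 and 3372 for infection on inulin, from 2029 and 2496 to 2881 and 1866 for diet under infection and from 1096 and 1641 to 1541 and 1260 for the interaction. The counts of changed genes stayed within 1.5 times their reported size except under the following. At an adjusted p under 0.01 they were 1465 for infection on the control diet, 66 for diet without infection, 2883 for diet under infection and 1549 for the interaction, as a stricter threshold must give fewer. For diet without infection, array weights gave 570 and its own 12 arrays 365. Fitting those 12 arrays alone leaves each log2 difference unchanged, so only the estimate of its error differed. The same kind of fit gave 3318 for diet under infection. Over genes above the median level, r between the infection responses was 0.709. The causes of the changes with array weights and in r were not tested. With each array left out in turn, the counts were 1992 to 3433 for infection on the control diet, 7094 to 7582 for infection on inulin, 90 to 274 for diet without infection, 3767 to 4717 for diet under infection and 2321 to 2993 for the interaction. For diet without infection, 90 was without inulin uninfected replicate 5, 92 without control uninfected replicate 3 and 274 without inulin infected replicate 4. The correlations ranged from 0.59 to 0.648 for the infection responses and from -0.048 to 0.024 for the diet effects. Without the 2 arrays the 5 counts were 3616, 7126, 204, 4662 and 2789, and with the poly-A covariate 2534, 5398, 188, 3434 and 2139.

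Of 128 list calls by camera, 125 kept their side of the threshold with quantile normalization, 127 with centring, 128 with the mean of the probe sets, 120 without the 2 arrays, 120 with the poly-A covariate, 110 by fry and 26 with an estimated correlation. Of the 106 that could be tested on genes above the median level, 87 did. With 1 array left out at a time, 3001 held and 71 did not. Among 218 values of named genes, the calls that changed were those of Nos2, Ido1, Retnlb and Il13 given in the report and of Mcpt1 for diet without infection under array weights (adjusted p = 0.049). With the replicate number as a block the counts were 2673, 7377, 156, 4437 and 2649, and Nos2 passed for infection on the control diet (0.045). Of 36 pairs of arrays with the same number 5 correlated above 0.1, with a mean r of 0.009 against -0.001 for other pairs. Background limits the dim genes: 6188 genes had a mean below that of the background probe sets.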

Other observations

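The family scan and the list of Paneth cell products were chosen after the result was seen. Clock genes went both ways with infection, and the list did not pass camera in either diet. Arntl, a core clock activator, fell by 1.20 (SE 0.19) on the control diet and fell by 2.02 (SE 0.19) on inulin, and Npas2, a partner of Arntl, fell by 2.93 (SE 0.26) on inulin. Dbp and Bhlhe41, chosen after their values were seen, rose by 1.58 (SE 0.25) and 0.95 (SE 0.32) on the control diet and by 0.99 (SE 0.25) and 1.94 (SE 0.32) on inulin. Of 16 clock genes 2 rose and 4 fell on the control diet (2 and 4 adjusted over the list alone; camera adjusted p = 0.37) and 3 rose and 4 fell on inulin (3 and 5 adjusted over the list alone; 0.43). Under infection 8 were lower on inulin and 1 was higher (8 and 1 adjusted over the list alone; 0.014, and 0.11 with an estimated correlation). Of 15 cell death and pyroptosis genes 4 rose and 1 fell on the control diet (5 and 2 adjusted over the list alone; camera adjusted p = 0.064), and 7 rose and 2 fell on inulin (7 and 2 adjusted over the list alone; 0.04, and adjusted p = 0.42 with an estimated correlation). The call on inulin was lost, at 0.05 to 0.079, without inulin uninfected replicate 2 or inulin infected replicate 2, 3, 5 or 6, and at 0.05 with centring and 0.16 over genes above the median level. Il18, an epithelial cytokine released by inflammasomes, fell by 2.25 (SE 0.32) on the control diet and fell by 4.16 (SE 0.32) on inulin. Gsdmc, which encodes a pore-forming gasdermin, rose by 0.99 (SE 0.18) with infection on the control diet and differed by -1.47 (SE 0.18) between infected mice on inulin and on the control diet.

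Paneth cell products, 18 of which were measured, were lower in infected mice on inulin than on the control diet in 10. With infection on inulin 1 rose and 1 fell, and the interaction was negative in 10. The list was written after Defa24, Itln1 and Mptx1 were seen. The 5 members kept for the reduced test share no symbol stem with those genes or with list members that other lists also hold. Of these 5, 0 passed in limma for diet under infection (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, camera adjusted p = 0.64).

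A scan of 312 families of genes that share a symbol stem called 30 for infection on the control diet, 38 for infection on inulin, 1 for diet without infection, 31 for diet under infection and 30 for the interaction, and the call of none of these was kept with an estimated correlation. The families below were chosen after their values were seen. On the control diet 11 of 22 Defa genes (alpha-defensins) rose with infection (median 0.80, camera adjusted p = 1.8e-11, and adjusted p = 0.16 with an estimated correlation), 8 of 17 Ces genes (carboxylesterases) fell (0.00014, and 0.32) and 5 of 10 Ccr genes (chemokine receptors) rose (0.00042, and 0.14). On inulin 10 of 13 Apol genes rose (median 1.92; 6.7e-05, and 0.27), 9 of 10 Klra genes (receptors of natural killer cells; median 2.34; 7.7e-05, and 0.27), 8 of 9 Slfn genes (median 2.37; 0.00012, and 0.42) and 8 of 8 Gimap genes (median 1.70; 0.0026, and 0.46). Under infection 20 of 48 Mrpl genes (mitochondrial ribosome) were higher on inulin (median 0.41; 2.9e-05, and 0.44) and 10 of 22 Defa genes were lower (1.3e-05, and 0.44). Members of the Defa and Klra families are near-identical in sequence, and probe sets that detect several of them are not told from one another here. The directions of these families were the same after quantile normalization and after centring.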
